A study of Homo sapiens with 12 samples.

How the data were processed

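Total RNA of PANC-1 cells was sequenced in 12 libraries, 6 groups of 2 biological replicates, after RNeasy extraction with DNase I and ScriptSeq library preparation, per the labels. The deposited values are counts, whole numbers of reads per gene in 1 column per library, and the authors name STAR 2.05b, edgeR and the genome build GRCh38 in their processing notes. Each table holds 60669 Ensembl identifiers and 4 summary entries for unmapped, multimapping, no-feature and ambiguous reads, and every table was checked for whole numbers. The strand setting of the counting and the annotation release are not stated. The planned comparison of count columns could not be run, since each library has 1 column. Symbols and positions came from GENCODE 29 and a symbol table, and 3742 identifiers had no name in them.

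Groups were taken from the titles and characteristics, in which the target is called AS1 in the titles and SIK3 in the characteristics. The condition words in the submitters' file names differ from the titles for 8 of the 12 libraries, and in them CLM was read as unstimulated by elimination. Groups, main tests, gene lists, the rule for named genes and most alternatives, the file-name conditions among them, were fixed before the data were examined. The omission of 4 libraries, the replicate block in list tests and with the file-name conditions, and some tests of explanations were chosen after seeing the data. Total gene counts ran from 13535825 to 22699756 per library, and multimapping reads from 4.94 to 45.3% of all reads.

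Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were left out by filterByExpr (minimum count 10), which kept 16695 genes, and library sizes were scaled by TMM. A quasi-likelihood fit of all 12 libraries, with 6 residual degrees of freedom and no block, gave 7 pairwise comparisons and 2 interactions, each adjusted over genes by Benjamini-Hochberg with a threshold of 0.05. The chi-square of the replicates within a group, 17.9 to 36.6 per degree of freedom, shows a spread above counting error. Levels are TMM-scaled CPM, given as mean ± SD of 2 libraries, and folds are from the fit. Where a group had no count, 3 counts over the group stood in for it and the fold is a lower bound.

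The replicate numbers were checked for pairing by correlating, across genes, the deviations of replicate 1 from the group mean between groups. All 15 pairs of groups exceeded 0.1 (0.35 to 0.53, median 0.421), so counts over all genes with the replicate number as a block are given beside those without it, for titles and file names, where they differ by more than 1.5 times, and list tests with the block where it changes a call whose p is printed. Genes are not independent replicates in this check.

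Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, each adjusted over the lists tested. The lists described are NF-κB feedback and signalling, cytokines and chemokines, adhesion and matrix remodelling, immediate early genes, anti-apoptotic and pro-apoptotic genes, CREB and CRTC targets, interferon-stimulated genes, antigen presentation and immune ligands, cell cycle and DNA replication, p53 targets, epithelial genes and mitochondrially encoded mRNAs. Named genes were SIK3, SIK1 and SIK2, up to 10 higher and 10 lower genes per comparison with the largest fold among those called, with a CPM of at least 1 in the higher group and no overlap between the groups, and up to 4 members of a described list with the smallest p. The overlap condition was dropped for interactions, and fewer were named where genes repeat.

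The fit was tested on simulated data with seeded changes. For the pair at TNF 30 min it recovered 7.5% of genes seeded at 1.5-fold, 61.2% at 2-fold and 95.5% at 4-fold, and for the 4 h interaction 3, 14.9 and 89.4%. Alternatives were the replicate block, DESeq2 1.42.0 size factors, library totals, the DESeq2 Wald test, limma voom, no filter, a stricter filter (CPM of at least 1 in at least 4 libraries), the libraries compared alone, an adjusted p under 0.01, an estimated correlation, each library left out in turn, and conditions from the file names. For no-feature reads, silent genes (CPM under 0.1 elsewhere) were sorted by place relative to expressed genes (CPM above 20), within 10 kb of an end, inside, or over 200 kb away. SIK3 was compared between siRNAs over all 924 splits of the libraries into equal groups. Figures and permutations were made in Python 3.11.15.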

Results

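RNA was sequenced from PANC-1 cells, a human pancreatic ductal adenocarcinoma line, transfected for 72 h with a control siRNA or with an siRNA against SIK3, a kinase of the salt-inducible family that phosphorylates CRTC coactivators and class IIa histone deacetylases. Cells were left unstimulated or given TNF-α, an inflammatory cytokine that activates NF-κB, at 100 ng/mL for 30 min or 4 h. The 6 groups by title held 2 biological replicates each, 12 libraries in all. Gene counts per library, replicate 1 then 2, were 19025746 and 14323580 for control siRNA unstimulated, 18743266 and 19003108 for SIK3 siRNA unstimulated, 17448085 and 13535825 for control siRNA with TNF 30 min, and 22699756 and 14384957 for SIK3 siRNA with TNF 30 min. They were 18567878 and 19783290 for control siRNA with TNF 4 h, and 14874894 and 18118651 for SIK3 siRNA with TNF 4 h. A gene with no count in a library could still lie at up to 0.132 to 0.222 CPM (read counts scaled to the library total, here 3 counts), and this limit covers counting error only.

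SIK3 (ENSG00000160584, chromosome 11, 116843402 to 117098437, minus strand, GRCh38), the gene targeted by the siRNA, did not follow the titles. In the libraries labelled control siRNA it was at 47.3 ± 18.4 CPM unstimulated (SD, n = 2), 49.7 ± 21.8 CPM after TNF 30 min and 20.6 ± 4.78 CPM after TNF 4 h. In those labelled SIK3 siRNA it was at 55.5 ± 18.5 CPM unstimulated, 19.3 ± 4.29 CPM after TNF 30 min and 20.5 ± 3.18 CPM after TNF 4 h. Unstimulated replicates 1 and 2 held 34.3 and 60.3 CPM with control siRNA and 42.4 and 68.6 CPM with SIK3 siRNA. After TNF 30 min they held 34.3 and 65.2 CPM with control siRNA and 16.3 and 22.4 CPM with SIK3 siRNA, and after TNF 4 h 17.2 and 24.0 CPM against 18.2 and 22.7 CPM. Pooled over the TNF times, the 6 libraries labelled SIK3 siRNA were not told apart from the 6 labelled control siRNA (mean log2 difference −0.354, exact permutation test, 2-sided, p = 0.431, 398 of 924 splits). The test ignores TNF time and replicate number, and at TNF 30 min SIK3 was lower under the SIK3 siRNA label. The condition words in the submitters' file names differ from the title for 8 libraries, in 4 of the 6 groups, and match it for 4 libraries. The file names give the libraries titled SIK3 siRNA unstimulated as control siRNA with TNF 30 min. They give those titled control siRNA with TNF 30 min as control siRNA with TNF 4 h. Libraries titled SIK3 siRNA with TNF 30 min are named SIK3 siRNA unstimulated. Those titled control siRNA with TNF 4 h are named SIK3 siRNA with TNF 30 min. Groups below are those of the titles, written as libraries labelled with a condition, and each comparison is also given its count with conditions from the file names. Such a count comes from another set of libraries, so it does not recheck the titled pair.

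**Figure D1:**
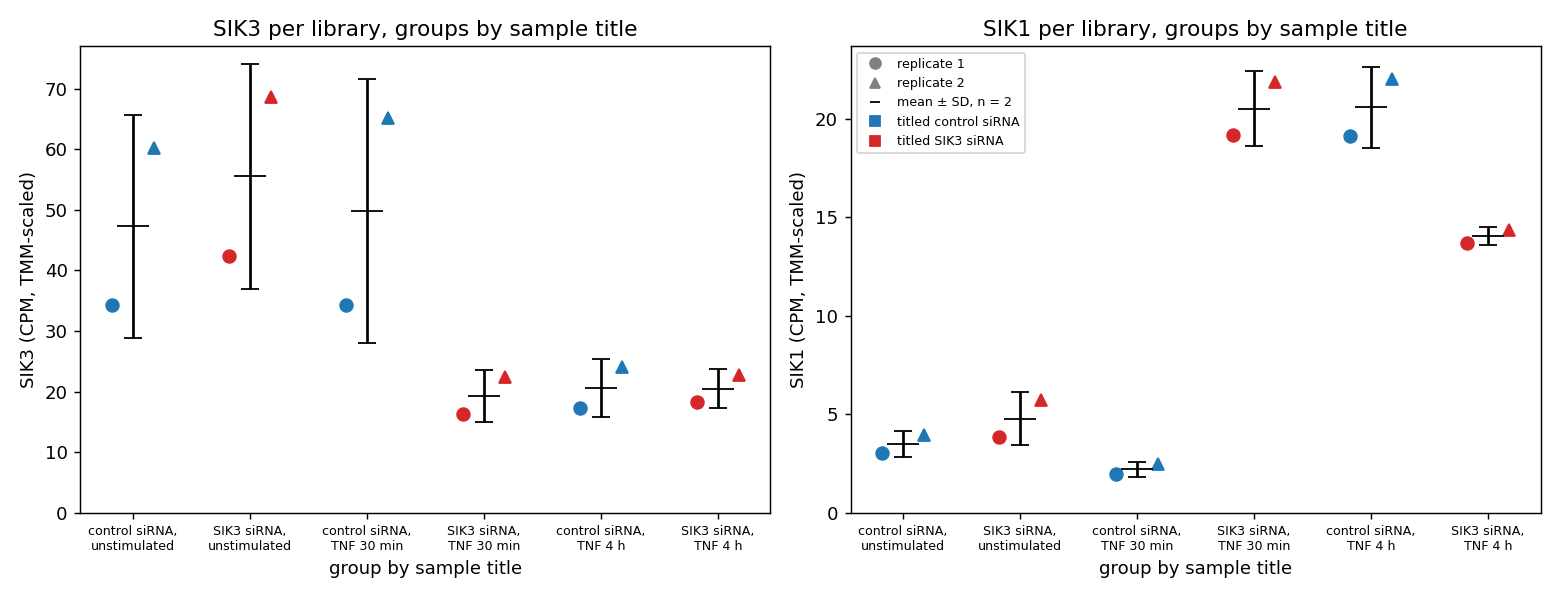
SIK3 and SIK1 in CPM (vertical axes) for each library (points) by the group in its title (horizontal axis), with mean ± SD (n = 2) as lines. SIK3 was at 16.3 to 24.0 CPM in the libraries labelled SIK3 siRNA with TNF 30 min, control siRNA with TNF 4 h and SIK3 siRNA with TNF 4 h, and at 34.3 to 68.6 CPM in the other libraries.

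The related kinases are SIK1 (ENSG00000142178, chromosome 21, 43414483 to 43427189, minus strand) and SIK2 (ENSG00000170145, chromosome 11, 111602391 to 111730853, plus strand). SIK1 was at 3.48 ± 0.66, 2.2 ± 0.36 and 20.6 ± 2.06 CPM in the unstimulated, TNF 30 min and TNF 4 h libraries labelled control siRNA, and at 4.78 ± 1.33, 20.5 ± 1.91 and 14.04 ± 0.46 CPM in those labelled SIK3 siRNA. Its near-identical copy held 28 counts over all libraries against 2428 for SIK1, and how reads were shared between them is not known. SIK2 lay between 36.8 ± 5.85 CPM (control siRNA, unstimulated) and 55.9 ± 9.11 CPM (SIK3 siRNA, TNF 30 min).

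What SIK3 siRNA does to unstimulated cells is asked, by title, by the pair of unstimulated groups. By file name this pair is control siRNA with TNF 30 min against control siRNA unstimulated. SIK3 was not lower in it under the SIK3 siRNA label. In the libraries labelled SIK3 siRNA, 11 of 34 measured immediate early genes, which encode short-lived transcription factors and signalling regulators, rose and 0 fell (camera adjusted p = 1.33e-67, and adjusted p = 0.00384 with an estimated correlation). EGR2 rose 8.51-fold, from 2.42 ± 0.579 to 20.4 ± 4.64 CPM (SD, n = 2, adjusted p = 0.00285), EGR4 7.31-fold (adjusted p = 0.038), NR4A1 6.31-fold (adjusted p = 0.00798) and IER2 2.99-fold (adjusted p = 0.000294). JUNB rose 2.92-fold, JUN 2.55-fold, ATF3 2.10-fold and the phosphatase gene DUSP1 2.02-fold. Of 22 cytokines and chemokines 6 rose (adjusted p = 0.00274 with an estimated correlation), with the neutrophil attractants CXCL3 at 23.1-fold, 23.2 ± 1.12 against 1.01 ± 0.0769 CPM, CXCL2 at 7.03-fold, CXCL1 at 3.73-fold and CXCL8 at 3.74-fold, TNF at 8.76-fold and the costimulatory ligand TNFSF9 at 7.58-fold. Among 16 members of NF-κB feedback and signalling 4 rose and 1 fell (adjusted p = 0.042 with an estimated correlation, test upward, though the median member stood at −0.06 on the log2 scale). NFKBIZ rose 6.42-fold to 301.0 ± 12.4 CPM, TNFAIP3, which ends NF-κB signalling, 4.06-fold and NFKBIA 2.95-fold. Among 15 CREB and CRTC targets 2 rose (adjusted p = 0.00274 with an estimated correlation), and SELE, an adhesion receptor, rose 4.08-fold, the interferon regulator IRF1 2.43-fold, GBP2 1.72-fold, SERPINA3 36.1-fold and the tight junction gene CLDN4 1.94-fold. The 4 genes that fell were ELOVL7 (1.86-fold lower), TRAF1 (1.83-fold lower), ZNF697 (1.56-fold lower) and WWC1 (1.46-fold lower).

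Across the 16695 genes tested, 49 passed in the unstimulated pair, 45 higher and 4 lower, and SIK3 itself differed by 0.24 on the log2 scale (edgeR quasi-likelihood, adjusted p = 1). With the replicate number as a block 464 passed, 303 higher and 161 lower, and with conditions from the file names 6449 passed (9746 with the block too), with the NF-κB list then at a median of −0.24 (1 higher, 5 lower). Immediate early genes by file name had a camera adjusted p of 0.13, or 0.87 with an estimated correlation (0.0346 and 0.771 with the block). Leaving out any 1 of the 4 libraries left 22 to 27 genes. Of 26 named genes called, 13 (TNF, EGR2, TNFSF9, NR4A1, ELOVL7, TRAF1, ZNF697, WWC1, CXCL8, SELE, CLDN4, EGR4 and GBP2) lost the call without at least 1 library, with adjusted p from 0.0516 to 0.453. The omissions were fitted without the replicate block, so a lost call can also carry the difference between replicates. Adjusted over the list alone, 24 immediate early genes (23 higher) and 9 cytokines and chemokines passed.

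By file name the next pair is SIK3 siRNA unstimulated against control siRNA with TNF 4 h. Its titles ask what SIK3 siRNA does after TNF 30 min. In the libraries so labelled, 28 of 28 cell cycle and DNA replication genes fell against control siRNA (adjusted p = 0.00569 with an estimated correlation). TOP2A, which untangles DNA for mitosis, was 13.6-fold lower, 53.4 ± 2.96 against 726.5 ± 11.2 CPM (SD, n = 2, adjusted p = 1.09e-07), the mitotic kinases AURKB 8.11-fold and BUB1 6.49-fold lower, and the replicative helicase gene MCM4 3.48-fold lower. Of 16 members of NF-κB feedback and signalling 13 fell (adjusted p = 0.00611 with an estimated correlation), TNFAIP3 13.1-fold, TRAF1 8.86-fold, NFKBIA 6.03-fold and CYLD 4.34-fold. Among the 22 cytokines and chemokines 18 fell and 1 rose (adjusted p = 0.0284 with an estimated correlation, 0.0656 with the replicate block too), CCL5 19.9-fold, CSF2 19.0-fold, CXCL3 7.81-fold and IL32 5.91-fold. Of 15 adhesion and matrix genes 10 fell and 2 rose (adjusted p = 0.0284 with an estimated correlation), and the endothelial-type adhesion genes SELE and VCAM1 were 540.8-fold and 102.5-fold lower, SELE at 0.358 ± 0.0256 against 199.5 ± 35.9 CPM. Of 15 CREB and CRTC targets 11 rose and 0 fell (adjusted p = 0.0284 with an estimated correlation, 0.0528 with the block too), SIK1 9.39-fold, BDNF 12.7-fold and AREG 5.93-fold.

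In the same pair, 9 of 12 anti-apoptotic genes fell (adjusted p = 0.156 with an estimated correlation, 0.0353 with the replicate block too), with XIAP 5.60-fold, BIRC3 4.88-fold, CFLAR 4.07-fold and SOD2 3.09-fold lower, and 11 of 21 pro-apoptotic genes fell (adjusted p = 0.212 with an estimated correlation), FAS 5.46-fold, BBC3 7.05-fold and APAF1 3.43-fold. In the list of antigen presentation and immune ligands 13 of 17 fell (adjusted p = 0.171 with an estimated correlation), HLA-F 5.92-fold, HLA-B 2.13-fold, TAP1 2.39-fold and PSMB10 4.92-fold. Interferon-stimulated genes went both ways, with 12 of 32 higher and 11 lower (camera adjusted p = 0.954), IFI6 9.53-fold higher and IRF1 13.2-fold lower. SNAI2, a transcription factor of epithelial-mesenchymal transition, was 51.5-fold higher (12.9 ± 2.85 against 0.258 ± 0.194 CPM), DIO2 40.6-fold, ADAMTS1 37.9-fold and SCG2 32.5-fold. RASSF5 was 73.0-fold lower. DUSP4 had no count in the libraries labelled control siRNA and was at least 18.9-fold higher, and SPIB had none in those labelled SIK3 siRNA and was at least 29.9-fold lower (3 counts over the group).

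Here 7096 of 16695 genes passed, 3452 higher and 3644 lower, and 6314 with conditions from the file names (9771 with the replicate block too), with antigen presentation then at a median of 0.28 on the log2 scale (5 higher, 3 lower). SIK3 was 2.58-fold lower (adjusted p = 0.0165), a call lost without control siRNA TNF 30 min replicate 2 (−0.81 on the log2 scale) or SIK3 siRNA TNF 30 min replicate 1 (−1.17). With the replicate block SIK3 stood at −1.32 (edgeR quasi-likelihood, adjusted p = 9.09e-10). Scaling by library totals gave 4364 higher and 2909 lower, and moved the median of all genes to 0.16 from 0.02 on the log2 scale. Without the 4 libraries whose SIK3 level goes against the title, an omission chosen after seeing the data, 6607 genes passed. None of these libraries is in this pair, so the omission is no test of the titles.

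After TNF 4 h the pair by title asks the same of a longer stimulus. By file name it is SIK3 siRNA with TNF 4 h against SIK3 siRNA with TNF 30 min. In the libraries labelled SIK3 siRNA, of 16 members of NF-κB feedback and signalling 12 rose (adjusted p = 0.00162 with an estimated correlation), TRAF1 5.80-fold, from 17.5 ± 1.31 to 101.6 ± 3.46 CPM (SD, n = 2, adjusted p = 5.57e-06), NFKB1 2.46-fold, CYLD 2.43-fold and NFKB2 2.34-fold. Of 22 cytokines and chemokines 9 rose (adjusted p = 0.0255 with an estimated correlation), CCL20 6.37-fold, CX3CL1 5.14-fold and CCL5 3.05-fold. Of 15 adhesion and matrix genes 9 rose (adjusted p = 0.00218 with an estimated correlation), SELE 6.74-fold, ICAM1 4.14-fold and SDC4 1.86-fold. Of 12 anti-apoptotic genes 7 rose (adjusted p = 0.0359 with an estimated correlation), SOD2 3.45-fold, BIRC3 3.17-fold and CFLAR 2.29-fold. Of 28 cell cycle and DNA replication genes 12 rose (adjusted p = 0.0359 with an estimated correlation, 0.0873 with the replicate block too), TYMS 1.64-fold, MCM7 1.61-fold, BIRC5 1.61-fold and RRM2 1.55-fold. Of 15 CREB and CRTC targets 4 fell (adjusted p = 0.0321 with an estimated correlation). FOS fell 3.30-fold, EGR2 12.8-fold, DIO2 4.33-fold, TXNIP 4.20-fold, OSR1 3.85-fold and KCNE4 9.24-fold. CDKN1A rose 2.56-fold, C1QTNF1 19.9-fold and SLC7A2 19.4-fold, and CDH16, with no count in the libraries labelled control siRNA, was at least 41.1-fold higher.

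In the TNF 4 h pair 1182 of 16695 genes passed, 825 higher and 357 lower, and SIK3 differed by −0.01 on the log2 scale (edgeR quasi-likelihood, adjusted p = 0.997). The replicate block gave 4646 (2472 higher), library totals 714 higher and 480 lower, and the file-name conditions 6596. With the file-name conditions these lists took the opposite direction, NF-κB feedback and signalling with 11 of 16 lower (median −0.74 on the log2 scale, adjusted p = 0.0484 with an estimated correlation, 0.109 with the replicate block too). Of cytokines 12 were lower and 2 higher (median −0.86), of adhesion genes 7 lower and 3 higher (−0.48), of anti-apoptotic genes 7 lower and 2 higher (−0.86), of cell cycle genes 25 lower (−1.45) and of CREB and CRTC targets 11 higher and 1 lower (1.56). TRAF1 was then at −1.62, CCL5 at −3.08, SELE at −5.07 and ICAM1 at −1.23. Leaving out any 1 of the 4 libraries left 418 to 515 genes, and TYMS, MCM7, RRM2, BIRC5, OSR1 and KCNE4 lost the call without at least 1 of them (adjusted p from 0.0546 to 0.139). In the libraries labelled SIK3 siRNA with TNF 4 h, 16.5 and 17.1% of reads fell in no annotated gene, against 8.35 to 10.5% in the other 10 libraries.

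The next pair is by file name control siRNA with TNF 4 h against control siRNA unstimulated. Its titles ask how cells with control siRNA respond to TNF within 30 min. In the libraries so labelled 13 of 16 members of NF-κB feedback and signalling rose (adjusted p = 0.000483 with an estimated correlation), TNFAIP3 7.23-fold, from 38.2 ± 3.09 to 275.9 ± 7.49 CPM (SD, n = 2, adjusted p = 9.92e-06), TRAF1 5.92-fold, NFKBIA 4.36-fold and NFKB1 2.49-fold. Among the 22 cytokines and chemokines 17 rose (adjusted p = 0.00104 with an estimated correlation), CSF2 23.1-fold, CXCL3 10.4-fold, CXCL8 10.3-fold and CCL5 9.89-fold. Of 15 adhesion and matrix genes 9 rose and 2 fell (adjusted p = 0.00104 with an estimated correlation), SELE 96.2-fold, ICAM1 6.85-fold to 2655 ± 364.8 CPM, SDC4 3.56-fold and the urokinase gene PLAU 2.65-fold. In the list of antigen presentation and immune ligands 12 of 17 rose (adjusted p = 0.0139 with an estimated correlation), HLA-F 7.79-fold, HLA-B 3.31-fold and HLA-E 1.85-fold. Of 32 interferon-stimulated genes 11 rose (adjusted p = 0.031 with an estimated correlation), IRF1 6.75-fold and GBP1 5.51-fold. Of 12 anti-apoptotic genes 7 rose (adjusted p = 0.0404 with an estimated correlation), SOD2 5.80-fold, BCL2A1 4.61-fold, CFLAR 2.73-fold and BIRC3 2.54-fold, and 5 of 12 p53 targets rose (adjusted p = 0.0139 with an estimated correlation). FAS rose 3.58-fold and BBC3 5.84-fold. The immediate early gene FOS fell 3.51-fold, PDK4 8.14-fold, GDF15 6.33-fold, BDNF 6.28-fold and OSR1 9.69-fold.

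In this pair 1501 of 16695 genes passed (edgeR quasi-likelihood), 923 higher and 578 lower, and 49 passed with conditions from the file names (464 with the replicate block too), with anti-apoptotic genes and antigen presentation then at medians of −0.10 and −0.13 on the log2 scale and 0 members called. The 49 come from other libraries, the unstimulated siRNA pair by title. The libraries of this pair keep their 1501 genes by file name, as TNF 4 h with control siRNA. The replicate block gave 3928 (1883 higher), library totals 820 higher and 825 lower with the median of all genes at −0.11 against −0.03 on the log2 scale, and leaving out any 1 of the 4 libraries 857 to 922. OSR1 lost the call without control siRNA TNF 30 min replicate 1 (−2.43 on the log2 scale). Without the 4 libraries whose SIK3 level goes against the title, none of which is in this pair, 1145 genes passed.

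The next pair is by file name SIK3 siRNA with TNF 30 min against control siRNA unstimulated. Its subject by title is the response of control cells to 4 h of TNF. In the libraries so labelled 28 of 28 cell cycle and DNA replication genes fell (adjusted p = 0.00764 with an estimated correlation), TOP2A 11.7-fold, from 753.8 ± 0.597 to 64.4 ± 2.99 CPM (SD, n = 2, adjusted p = 1.72e-07), BUB1 6.64-fold, AURKB 6.01-fold and MCM4 3.39-fold. CEP55, needed for the final cut of cell division, fell 13.2-fold and HMMR 11.7-fold. Of 34 immediate early genes 21 rose and 1 fell (adjusted p = 0.429 with an estimated correlation, 0.0373 with the replicate block too), NR4A1 20.1-fold, DUSP5 5.37-fold, DUSP1 3.10-fold, ATF3 2.24-fold and JUN 2.24-fold. Of 15 CREB and CRTC targets 9 rose (adjusted p = 0.0321 with an estimated correlation), SIK1 5.95-fold. Members of NF-κB feedback and signalling went both ways, with 5 of 16 higher and 5 lower (camera adjusted p = 0.646), NFKBIZ 2.78-fold higher, TRAF1 3.01-fold lower and NFKBIE 1.97-fold lower. Of 22 cytokines and chemokines 6 rose and 6 fell (camera adjusted p = 0.291), CXCL3 9.99-fold, CXCL2 4.24-fold and CXCL1 3.15-fold higher. Of 11 epithelial genes 3 fell (camera adjusted p = 0.175), ESRP1 4.25-fold and CDH1, the E-cadherin gene, 2.44-fold. XIAP fell 4.74-fold, BIRC3 2.36-fold and CYP1A1 15.0-fold, and DIO2 rose 34.1-fold.

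In this pair 6330 of 16695 genes passed, 3037 higher and 3293 lower, 9648 with the replicate block and 1501 with conditions from the file names (3928 with both), with CREB and CRTC targets then at a median of −0.34 on the log2 scale (2 higher, 3 lower). SIK3 fell 2.29-fold in these libraries labelled control siRNA (edgeR quasi-likelihood, adjusted p = 0.0324), a call lost without unstimulated replicate 2 (−0.75 on the log2 scale), TNF 4 h replicate 1 (−0.99) or TNF 4 h replicate 2 (−1.47). With the replicate block SIK3 stood at −1.17 (edgeR quasi-likelihood, adjusted p = 4.86e-09). SIK2 rose 1.46-fold (adjusted p = 0.0421), a call also lost without a library, and adjusted p where either call was lost ranged from 0.0553 to 0.309.

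The same times were compared in the libraries labelled SIK3 siRNA, of which the unstimulated ones did not hold less SIK3 than those labelled control siRNA (42.4 and 68.6 against 34.3 and 60.3 CPM). The file names give these unstimulated libraries as control siRNA with TNF 30 min, and those labelled TNF 30 min as SIK3 siRNA unstimulated. After TNF 30 min 27 of 28 cell cycle and DNA replication genes fell (adjusted p = 0.00437 with an estimated correlation), TOP2A 14.9-fold, from 793.8 ± 27.3 to 53.4 ± 2.96 CPM (SD, n = 2, adjusted p = 8.41e-08), BUB1 6.83-fold and AURKB 6.74-fold. Cytokines and chemokines fell for 12 of 22 members and rose for 2 (adjusted p = 0.437 with an estimated correlation), CXCL3 17.2-fold and TNF 14.9-fold lower. Of 34 immediate early genes 16 fell and 9 rose (adjusted p = 0.798 with an estimated correlation), IER2 5.17-fold and JUNB 4.56-fold lower and DUSP5 4.53-fold higher. Of 16 members of NF-κB feedback and signalling 6 fell and 4 rose (camera adjusted p = 0.14, 0.0331 with the replicate block, and 0.588 with the block and an estimated correlation), NFKBIZ 7.78-fold, TNFAIP3 7.36-fold and NFKBIA 4.09-fold lower. Of 32 interferon-stimulated genes 21 rose and 5 fell (adjusted p = 0.437 with an estimated correlation), IFI6 10.5-fold and the antiviral GTPase MX1 9.37-fold higher. SNAI2 rose 38.6-fold, and SELE fell 22.9-fold and SERPINA3 24.4-fold.

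The TNF 4 h pair labelled SIK3 siRNA is by file name SIK3 siRNA with TNF 4 h against control siRNA with the shorter TNF time. It then differs in siRNA as well as time, so its changes cannot be put down to TNF alone. After TNF 4 h in the libraries labelled SIK3 siRNA, 27 of 28 cell cycle and DNA replication genes fell (adjusted p = 0.0147 with an estimated correlation), TOP2A 9.75-fold and BUB1 4.69-fold. Of 15 adhesion and matrix genes 12 rose and 1 fell (adjusted p = 0.113 with an estimated correlation), PLAUR, the urokinase receptor gene, 3.70-fold, from 5.09 ± 0.45 to 18.9 ± 0.849 CPM (SD, n = 2, adjusted p = 2.01e-05). Of 16 members of NF-κB feedback and signalling 7 rose and 1 fell (adjusted p = 0.161 with an estimated correlation), TRAF1 3.53-fold, RELB 2.34-fold and NFKB1 2.32-fold higher and NFKBIZ 2.56-fold lower. Of 32 interferon-stimulated genes 19 rose and 4 fell (adjusted p = 0.327 with an estimated correlation), MX1 6.82-fold, IFI6 6.01-fold and GBP1 5.63-fold higher. In the list of antigen presentation and immune ligands 11 of 17 rose (adjusted p = 0.421 with an estimated correlation), HLA-B 2.38-fold and HLA-E 2.12-fold. Of 12 anti-apoptotic genes 7 rose and 2 fell (camera adjusted p = 0.0657, 0.00466 with the replicate block, and 0.348 with the block and an estimated correlation), SOD2 5.47-fold higher and XIAP 3.61-fold lower. RCN2 fell 10.9-fold. No-feature reads in these TNF 4 h libraries were the 16.5 and 17.1% given above.

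In all, 6687 of 16695 genes passed after TNF 30 min (3283 higher, 3404 lower) and 6980 after TNF 4 h (3553 higher, 3427 lower), against 25 and 738 with conditions from the file names (563 and 3642 with the replicate block too). By file name cytokines stood at a median of 0.08 on the log2 scale after TNF 30 min (2 higher), immediate early genes at 0.65 (8 higher), interferon-stimulated genes at −0.14 (1 higher) and the cell cycle list at 0.16 (0 called), and at 0.58 after TNF 4 h (14 higher). SIK3 fell 2.88-fold after TNF 30 min (edgeR quasi-likelihood, adjusted p = 0.0101) and 2.71-fold after TNF 4 h (adjusted p = 0.0132). The first call was lost without unstimulated replicate 2 (−1.16 on the log2 scale) or TNF 30 min replicate 1 (−1.34), and the second without unstimulated replicate 2 (−1.07) or TNF 4 h replicate 1 (−1.31). With the replicate block SIK3 stood at −1.50 and −1.43 (edgeR quasi-likelihood, adjusted p = 7.85e-11 and 2.2e-10).

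Whether the response to TNF differs between the siRNAs was tested by title as an interaction, on the log2 scale, for each time. By file name neither test is an interaction. The 30 min test then sets SIK3 siRNA unstimulated minus control siRNA with TNF 30 min against control siRNA with TNF 4 h minus control siRNA unstimulated. The 4 h test sets SIK3 siRNA with TNF 4 h minus control siRNA with TNF 30 min against SIK3 siRNA with TNF 30 min minus control siRNA unstimulated. At 30 min 13 of 16 members of NF-κB feedback and signalling were lower (adjusted p = 0.0029 with an estimated correlation), TNFAIP3 by −5.73 ± 0.24 (SE, edgeR quasi-likelihood, adjusted p = 1.07e-06) and NFKBIA by −4.15 ± 0.17. Of 22 cytokines and chemokines 15 were lower and 1 higher (adjusted p = 0.01 with an estimated correlation), TNF by −7.75 and CXCL3 by −7.49, and SELE differed by −11.11. Of 28 cell cycle and DNA replication genes 27 were lower (adjusted p = 0.0029 with an estimated correlation), TOP2A by −3.84 ± 0.13, while SNAI2 was higher by 6.07. At 4 h 7 of 16 members of NF-κB feedback and signalling were higher and 1 lower (adjusted p = 0.00896 with an estimated correlation), TRAF1 by 3.41 ± 0.13. Of 15 adhesion and matrix genes 7 were higher (adjusted p = 0.00593 with an estimated correlation). Of 34 immediate early genes 14 were lower and 2 higher (adjusted p = 0.0673 with an estimated correlation, 0.00811 with the replicate block too), EGR2 by −6.76, EGR3 by −4.22, NR4A1 by −3.78 and IER2 by −2.44. Of 15 CREB and CRTC targets 5 were lower (adjusted p = 0.00593 with an estimated correlation). ID2, an inhibitor of basic helix-loop-helix factors, was higher by 3.66, SLC7A2 higher by 4.53 and SERPINA3 lower by −3.74.

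At 30 min 4760 of 16695 genes passed this test, 2164 higher and 2596 lower, and 8415 with the replicate block. Library totals gave 2931 higher and 2042 lower, with the median of all genes at 0.18 against 0.01 on the log2 scale. With conditions from the file names edgeR quasi-likelihood called 0 genes, 317 had an unadjusted p under 0.05, DESeq2 called 6, and 44 passed with the replicate block, and the cell cycle list stood at a median of 0.16. SIK3 differed by −1.60 on the log2 scale (adjusted p = 0.0484), a call lost in 5 of the 8 omissions of 1 library (−1.05 without control siRNA TNF 30 min replicate 2, −1.23 without SIK3 siRNA unstimulated replicate 2, −1.27 without control siRNA unstimulated replicate 1, −1.41 and −1.83 without SIK3 siRNA TNF 30 min replicates 1 and 2). With the replicate block SIK3 differed by −1.56 (edgeR quasi-likelihood, adjusted p = 1.28e-08). At 4 h 576 genes passed, 381 higher and 195 lower, 3374 with the replicate block and 261 with conditions from the file names (1996 with both), in a test that includes the libraries with 16.5 and 17.1% no-feature reads. By file name the 4 h direction turned, with the NF-κB list at a median of −0.40 on the log2 scale (2 lower, adjusted p = 0.0136 with an estimated correlation), TRAF1 at −1.04 (adjusted p = 0.00598), adhesion at −0.33 (2 lower, 1 higher) and CREB and CRTC targets at 0.56 (2 higher). Leaving out any 1 of the 8 libraries left 242 to 343, SIK3 differed by −0.24 (adjusted p = 0.925), and SERPINA3, SLC7A2 and EGR3 lost the call without at least 1 library (adjusted p from 0.0613 to 0.121).

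**Figure D2:**
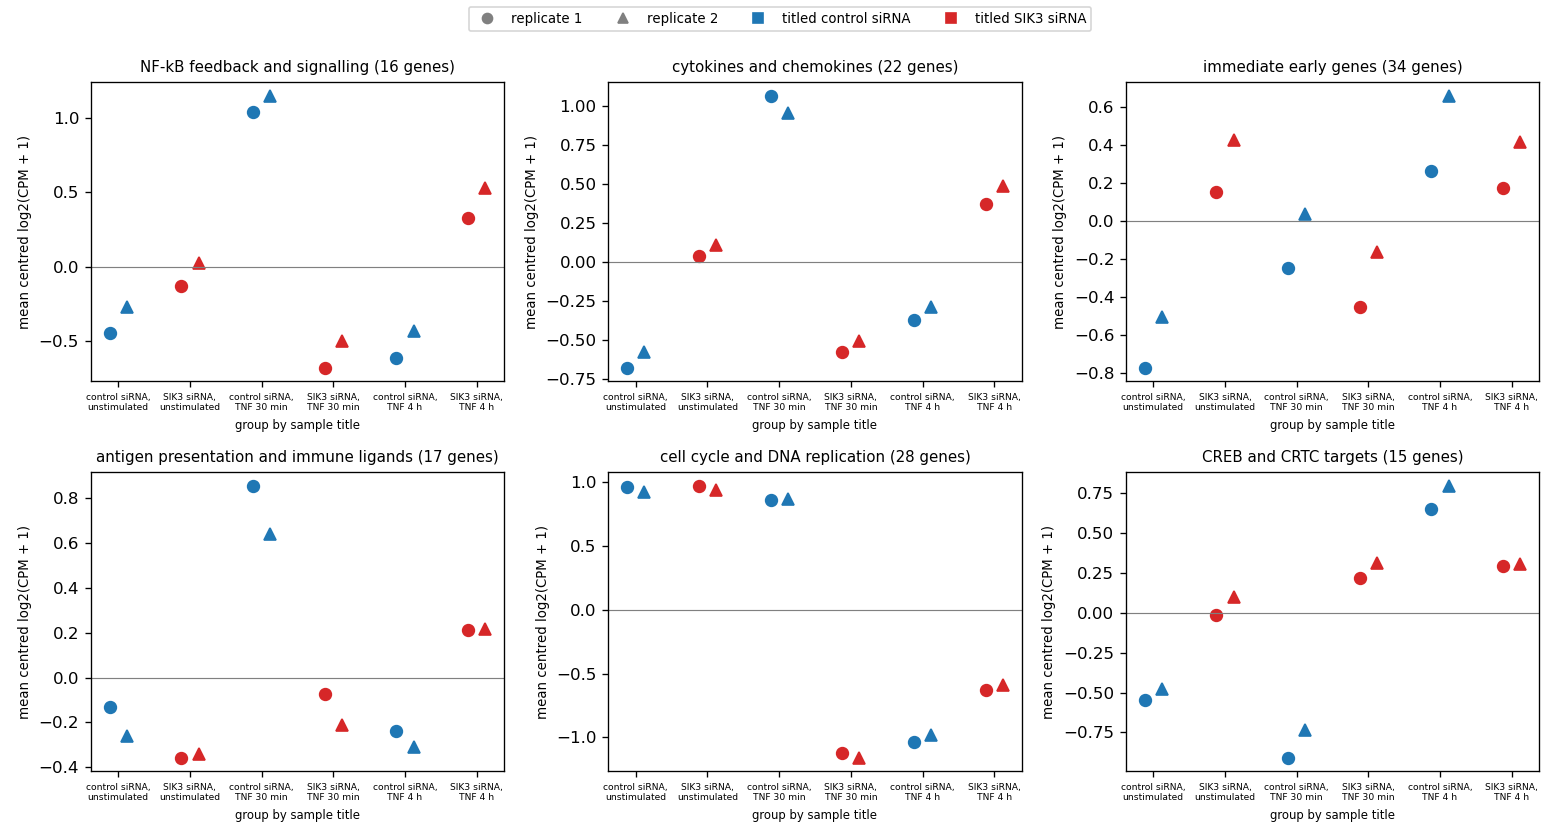
Mean level of 6 gene lists in each library (points, log2(CPM + 1) centred per gene over the 12 libraries, vertical axes) by the group in the title (horizontal axis). NF-κB feedback and signalling stood at 1.04 and 1.15 in the libraries labelled control siRNA with TNF 30 min and at 0.33 and 0.53 in those labelled SIK3 siRNA with TNF 4 h, and at 0.03 or below in the other libraries.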

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

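The tests of interaction and the list of places examined for no-feature reads past 3′ ends, before 5′ ends and inside genes were set before their values were seen, and the test of genomic DNA was chosen after the result was seen.

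The interaction tests by title use libraries that by file name form no interaction. By title, the response to TNF differed between the libraries labelled SIK3 siRNA and control siRNA for 4760 genes at 30 min and 576 genes at 4 h, by a test of the difference itself (edgeR quasi-likelihood). With the replicate block they were 8415 and 3374, with conditions from the file names 0 (317 at an unadjusted p under 0.05, and 6 by DESeq2) and 261, and with both 44 and 1996.

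Reads in no annotated gene made up 16.5 and 17.1% of all reads in replicates 1 and 2 labelled SIK3 siRNA with TNF 4 h, above the highest control-labelled library (10.19%), in a measure that no comparison uses. Silent genes rose by factors of 2.42 and 2.46 just past the 3′ ends of expressed genes, 2.58 and 2.81 inside them, 1.83 and 1.66 just before 5′ ends and 1.19 and 1.399 far away. Genomic DNA was taken to raise all places by a like factor, and is argued against as the whole cause by a rise past 3′ ends at least 1.759 times that far away. Levels in the other 10 libraries were unlike, 9.49 CPM over 336 genes past 3′ ends and 51.73 CPM over 9296 far away. Factors thus do not give the reads added, and a part of the rise may still come from genomic DNA. The strand setting of the counts is not stated, so the other strand cannot separate genomic DNA from reads past 3′ ends. The other strand past 3′ ends rose by 1.695 and 1.955, 1.428 and 1.397 times that far away. That rise is not particular to these libraries. The libraries labelled control siRNA with TNF 30 min, with 10.19 and 8.98% no-feature reads, had factors of 1.403 and 1.747 on the other strand and 1.215 and 1.283 far away. More unspliced RNA is a candidate explanation, since the factor inside genes was up to 1.141 times that past 3′ ends, whereas reads running past 3′ ends cannot be told apart from it, with a factor 1.322 and 1.483 times that before 5′ ends, between the bounds set for either outcome. Both libraries are one siRNA and time, so a biological change in transcription at that condition stays open and untested.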

How the results depend on the processing

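The omission of the 4 libraries whose SIK3 level goes against the title, and the replicate block in list tests and with the file-name conditions, were chosen after seeing the data, and the other alternatives were planned. The comparison of count columns by strand was not run, since each library has 1 column. Of 2642 alternative values of the named genes with the titles kept, 2624 had the main direction, 128 of them past the threshold no longer, and 18 were reversed. With the titles replaced by the file-name conditions, 107 of 209 named values were reversed, and 88 of the 209 were past the threshold no longer (55 of them reversed) and 5 newly passed it (2 of them reversed). Leaving out a library leaves a group with 1, which is then assumed to vary like the other groups. SIK3 was higher in replicate 2 of every group, so its value after an omission without the block also carries the difference between replicates. All omissions were fitted without the block, so calls lost for other genes can carry such a difference too. Depth limits the lowest levels, as a gene with no count could lie at up to 0.132 to 0.222 CPM. Seeded 2-fold changes were recovered in 61.2% of genes for the pair at TNF 30 min and in 14.9% for the 4 h interaction, in simulations that did not vary depth. The replicate block changed no call of a named gene except 6 values of SIK1 and SIK2 that newly passed. Without the 4 doubted libraries 6607 genes passed in the siRNA pair at TNF 30 min and 1145 in TNF 30 min with control siRNA. Neither comparison contains these libraries, so the omission changes only the filter, the scaling and the shared spread. It cannot test the titles, as the libraries labelled TNF 30 min stay in and their file names also differ from the titles. A stricter threshold calls fewer genes by construction, and fits with fewer libraries hold less data on the spread. For the other changes the cause was not tested.

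With the replicate number as a block, 464 genes passed in the unstimulated siRNA pair, 4646 in the siRNA pair at TNF 4 h, 3928 in TNF 30 min with control siRNA, 9648 in TNF 4 h with control siRNA, 8415 in the 30 min interaction and 3374 in the 4 h interaction. At an adjusted p under 0.01, 27 genes passed in the unstimulated siRNA pair, 483 in the siRNA pair at TNF 4 h, 802 in TNF 30 min with control siRNA, 4182 in TNF 4 h with control siRNA, 2834 in the 30 min interaction and 218 in the 4 h interaction. With the fit limited to the libraries compared, 14 genes passed in the unstimulated siRNA pair, 457 in the siRNA pair at TNF 4 h, 614 in TNF 30 min with control siRNA and 368 in the 4 h interaction. With the DESeq2 Wald test, 85 genes passed in the unstimulated siRNA pair. Without the filter on low counts, 101 genes passed in the unstimulated siRNA pair and 888 in the 4 h interaction. With conditions from the file names, 6449 genes passed in the unstimulated siRNA pair, 6596 in the siRNA pair at TNF 4 h, 49 in TNF 30 min with control siRNA, 1501 in TNF 4 h with control siRNA, 25 in TNF 30 min with SIK3 siRNA, 738 in TNF 4 h with SIK3 siRNA, 0 in the 30 min interaction and 261 in the 4 h interaction. With these conditions and the replicate block the counts were 9746, 9813, 464, 3928, 563, 3642, 44 and 1996 in that order, and with these conditions and any 1 library left out 4835 to 5262, 4766 to 5237, 22 to 27, 857 to 922, 6 to 11, 212 to 273, 0 in each and 61 to 116. With the replicate block in camera, 8 gene lists passed in the unstimulated siRNA pair in place of 5. The lists so gained did not pass with the block and an estimated correlation (camera adjusted p from 0.164 to 0.489). With an estimated correlation in camera, 5 of 9 gene lists passed in the siRNA pair at TNF 30 min, 2 of 4 in TNF 4 h with control siRNA, 1 of 4 in TNF 30 min with SIK3 siRNA, 1 of 8 in TNF 4 h with SIK3 siRNA, 4 of 9 in the 30 min interaction and 3 of 9 in the 4 h interaction.

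SIK3 in the siRNA pair at TNF 4 h went from −0.008 to 0.007 with limma voom and 0.009 with the stricter filter. SIK2 in the siRNA pair at TNF 4 h went from 0.006 to −0.018 with the DESeq2 Wald test, −0.019 with DESeq2 size factors, −0.044 with library totals and −0.025 without a filter. SIK3 in TNF 30 min with control siRNA went from 0.073 to −0.006 with library totals. SIK3 in the 30 min interaction went from −1.60 to −1.58 with limma voom, −1.44 with library totals and −1.58 with only the libraries compared. Leaving out 1 library at a time gave 22 to 27 genes in the unstimulated siRNA pair, 5606 to 5763 genes in the siRNA pair at TNF 30 min, 418 to 515 genes in the siRNA pair at TNF 4 h, 857 to 922 genes in TNF 30 min with control siRNA, 4849 to 5081 genes in TNF 4 h with control siRNA, 4901 to 5143 genes in TNF 30 min with SIK3 siRNA, 5091 to 5482 genes in TNF 4 h with SIK3 siRNA, 3697 to 4095 genes in the 30 min interaction and 242 to 343 genes in the 4 h interaction. The log2 value of SIK3 then ranged from −0.16 to 0.71 in the unstimulated siRNA pair, from −1.78 to −0.81 in the siRNA pair at TNF 30 min, from −0.23 to 0.25 in the siRNA pair at TNF 4 h, from −0.47 to 0.53 in TNF 30 min with control siRNA, from −1.57 to −0.75 in TNF 4 h with control siRNA, from −1.87 to −1.16 in TNF 30 min with SIK3 siRNA, from −1.77 to −1.07 in TNF 4 h with SIK3 siRNA, from −2.09 to −1.05 in the 30 min interaction and from −0.72 to 0.15 in the 4 h interaction. SIK2 ranged from −0.19 to 0.23 in the siRNA pair at TNF 4 h.

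With conditions from the file names, these log2 values took the opposite sign. In the unstimulated siRNA pair, SIK3 −1.29, TNF −0.77, NFKBIZ −0.28, ELOVL7 1.49, NFKBIA −0.47, TNFAIP3 −0.86, JUNB −0.64, IER2 −0.79, ATF3 −0.18, IRF1 −0.97, SELE −2.49 and CLDN4 −0.21. In the siRNA pair at TNF 30 min, SPIB 3.003, SOD2 0.67, HLA-F 0.36, HLA-B 0.55 and TAP1 0.084. In the siRNA pair at TNF 4 h, SIK1 2.69, C1QTNF1 −2.33, EGR2 1.02, DIO2 3.52, OSR1 2.82, TRAF1 −1.62, NFKB1 −0.37, CYLD −1.17, NFKB2 −0.73, CCL5 −3.08, CX3CL1 −1.04, CCL20 −1.06, SDC4 −1.24, SELE −5.07, ICAM1 −1.23, SOD2 −0.20, BIRC3 −0.92, CFLAR −0.98, TYMS −1.22, MCM7 −1.40, RRM2 −1.50, BIRC5 −1.69, FOS 0.88, CDKN1A −1.29, KCNE4 0.76 and SLC7A2 −1.02. In TNF 30 min with control siRNA, SIK1 0.47, OSR1 0.014, PDK4 0.26, GDF15 0.42, BDNF 0.31, TRAF1 −0.87, NFKB1 −0.26, CCL5 −0.19, ICAM1 −0.12, SOD2 −0.11, BCL2A1 −0.33, BIRC3 −0.13, GBP1 −0.20, HLA-B −0.17, HLA-F −0.24, HLA-E −0.09, FAS −0.32 and FOS 0.97. In TNF 4 h with control siRNA, SIK3 0.073, SIK1 −0.67, DIO2 −0.53, CEP55 0.056, AURKB 0.27, MCM4 0.033, TRAF1 2.57, NFKBIE 1.14, CDH1 0.014, XIAP 0.073 and BIRC3 1.34. In TNF 30 min with SIK3 siRNA, SIK3 0.10, SIK2 −0.054, SNAI2 −0.55, SERPINA3 1.35, SELE 1.25, CXCL3 2.90, NFKBIZ 1.76, TNFAIP3 1.39, NFKBIA 0.95, JUNB 1.52, IER2 1.43, DUSP5 −0.17, TOP2A 0.27, BUB1 0.074, AURKB 0.16, IFI6 −0.17, MX1 −0.084 and TNF 1.89. In TNF 4 h with SIK3 siRNA, SIK3 0.092, SIK1 −0.54, SIK2 −0.048, NFKBIZ 1.61, TOP2A 0.61, BUB1 0.54, XIAP 0.57, IFI6 −0.80 and MX1 −0.46. In the 30 min interaction, TOP2A 0.20 and SNAI2 −0.17. In the 4 h interaction, SIK3 0.02, EGR2 1.01, NR4A1 0.57, TRAF1 −1.04, IER2 0.44 and SLC7A2 −0.21. SIK3 with these conditions stood at −1.27 in the siRNA pair at TNF 4 h and −0.13 in the 30 min interaction. SPIB had 2 counts in all in that pair, so no fold is read from it. These values compare other libraries than the titles do, by construction.

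Leaving out 1 library moved these log2 values by title more than 1.5-fold. SERPINA3 in the unstimulated siRNA pair went from 5.18 to 5.90 without control siRNA replicate 1. In the siRNA pair at TNF 30 min SNAI2 went from 5.69 to 4.97 and 6.67 without control siRNA replicates 1 and 2, RASSF5 from −6.19 to −5.55 and −7.00 without SIK3 siRNA replicates 1 and 2, and DUSP4, a bound in the text, from 7.90 to 7.30 without SIK3 siRNA replicate 1. In the siRNA pair at TNF 4 h, without control siRNA replicates 1 and 2, C1QTNF1 went from 4.32 to 3.69 and 5.495 and SLC7A2 from 4.28 to 8.17 and 3.30, and SELE went from 2.75 to 3.38 without replicate 2. In TNF 30 min with control siRNA OSR1 went from −3.28 to −2.43 and −4.70 without TNF 30 min replicates 1 and 2, and CSF2 from 4.53 to 3.92 and 5.31 without unstimulated replicates 1 and 2. SNAI2 in the 30 min interaction went from 6.07 to 5.35 and 7.05 without control siRNA TNF 30 min replicates 1 and 2. In the 4 h interaction SLC7A2 went from 4.53 to 8.41 and 3.54 without control siRNA TNF 4 h replicates 1 and 2, SERPINA3 from −3.74 to −4.46 without control siRNA unstimulated replicate 1 and −3.13 without control siRNA TNF 4 h replicate 2, and EGR3 from −4.22 to −3.61 without SIK3 siRNA unstimulated replicate 2.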

Other observations

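Reading the conditions from the file names was planned, as was the test of a mislabelled sample, and its fits with the replicate block and the tests of a failed knockdown, of TNF lowering SIK3 (2 parts) and of it with an siRNA without effect, of raised unstimulated levels and of a shift of all genes were chosen after the result was seen.

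If the file names give the conditions, which is a hypothesis, SIK3 siRNA may lower the division programme at every time, with 6449 genes called in the unstimulated pair, 6314 at TNF 30 min and 6596 at TNF 4 h (9746, 9771 and 9813 with the replicate block). Of 28 cell cycle and DNA replication genes 27, 28 and 25 were lower, with adjusted p of 0.00535, 0.00597 and 0.0125 with an estimated correlation, and TOP2A changed by −3.82 on the log2 scale unstimulated and by −3.62 at TNF 30 min. SIK3 itself changed by −1.29, −1.43 and −1.27 (edgeR quasi-likelihood, adjusted p = 0.0231, 0.0146 and 0.0244), and SIK1 by 2.57, 2.10 and 2.69. The SIK3 calls were lost without control siRNA replicate 2 (−0.85, −1.06 and −0.74) or SIK3 siRNA replicate 1 (−1.09, −1.23 and −1.13) and at TNF 4 h also without SIK3 siRNA replicate 2 (−1.45), with adjusted p from 0.0684 to 0.188, and with the replicate block adjusted p was 2.07e-09, 1.66e-10 and 3.54e-09. SNAI2 was higher by 4.89, 4.73 and 4.37 (3.66 and 5.34 at TNF 4 h without control siRNA replicate 1 or 2), and of 15 CREB and CRTC targets 9, 8 and 11 were higher, with adjusted p of 0.16, 0.233 and 0.034 with an estimated correlation. A single siRNA sequence was used, so effects on other targets stay open.

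Under the same reading TNF for 30 min called 49 genes with control siRNA (45 higher) and 25 with SIK3 siRNA (23 higher), against 464 (303 higher) and 563 (279 higher) with the replicate block and 22 to 27 and 6 to 11 with any 1 of the 4 libraries left out. EGR2 (3.09 and 4.21 on the log2 scale), CXCL3 (4.53 and 2.90) and NFKBIZ (2.68 and 1.76) were higher with either siRNA, and EGR2 lost the call with control siRNA without unstimulated replicate 1 (2.85, adjusted p = 0.0739). TNF for 4 h called 1501 and 738 genes (3928 and 3642 with the block, 857 to 922 and 212 to 273 with any 1 library left out), with 13 and 11 of 16 members of NF-κB feedback and signalling higher. The 4 h interaction called 261 genes (1996 with the block, 61 to 116 with any 1 of the 8 libraries left out), among them CCL5 (−2.07), MX1 (−1.83), HLA-B (−1.28), TRAF1 (−1.04), FOS (1.96) and ID2 (3.49). Of 28 cell cycle and DNA replication genes 6 were higher in it, 25 with the block (adjusted p = 0.0136 with an estimated correlation, 0.0288 with the block too).

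SIK3 and TNF targets per library do not follow the titles, as by file name the lowest control library held 1.43 times the SIK3 of the highest SIK3 siRNA library (exact permutation p = 0.00216, 2 of 924 splits, the smallest these splits can give), against 0.251 by title, and the 4 libraries named 4 h held the highest medians of the NF-κB list (0.43 or more, others −0.11 or less). Wrong titles in 4 groups are therefore a candidate explanation, in a test written in advance that could have come out the other way, and an siRNA that failed in the unstimulated libraries does not by itself account for the log2 change of −1.19 in SIK3 in libraries titled control siRNA with TNF 4 h, though that call is lost in 3 of 4 omissions of a library and its bound was set after the value was seen. With the replicate block that change was −1.17 (edgeR quasi-likelihood, adjusted p = 4.86e-09). Over all genes tested, the axis of largest variation between libraries (first principal component, 53.6% of variance) divided them as the siRNA words of the file names do. Libraries named SIK3 siRNA stood at 46.8 to 57.4 on it and those named control siRNA at −55.5 to −49.2. The SIK3 level divides the libraries in the same way, so this axis does not separate wrong titles from a fall of SIK3 under TNF. TNF lowering SIK3 by 4 h with correct titles cannot be told apart from wrong titles for the TNF 4 h libraries, since the NF-κB list had a median of −0.31 there with quartiles of −0.54 and 0.31. For the unstimulated libraries, which had no TNF by title, it would need a working siRNA, and SIK3 stood 0.24 ± 0.37 (SE, log2) higher under the SIK3 siRNA label, where 2 SE reach −0.504, just past the bound of −0.5, so that this part cannot be told apart by the main fit. In the planned fit with the replicate block SIK3 stood 0.24 ± 0.098 higher, and 2 SE reach down to 0.048. These values lie above −0.5 and argue against this part for the unstimulated libraries, though the bound was set after the result was seen. TNF lowering SIK3 together with an siRNA without effect is argued against by 49 genes called between the unstimulated groups (45 higher, and 14 called with only these libraries fitted). Among them were CXCL3 (4.53), NFKBIZ (2.68) and EGR2 (3.09, and 2.85 without control siRNA unstimulated replicate 1, where its call is lost). Up to 7 unchanged genes were called in simulations, the bound used. Those simulations were of other comparisons and had no replicate effect, so they give no count of false calls for this pair. Passing their bound therefore decides nothing, and the argument rests on the calls themselves at an adjusted p under 0.05. An siRNA that missed SIK3 and changed other genes was not tested and stays open.

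Under the file-name reading the NF-κB list responded less to TNF 4 h with SIK3 siRNA, with a median interaction of −0.40 (−0.50 to −0.37 with any 1 library left out; adjusted p = 0.0136 with an estimated correlation, 0.0288 with the replicate block too), and the medians of cytokines and chemokines (−0.65, −0.86 to −0.49, adjusted p 0.0221 and 0.0702 with the block), interferon-stimulated genes (−0.60, −0.74 to −0.505, adjusted p 0.0221 and 0.0288) and antigen presentation and immune ligands (−0.58, −0.73 to −0.45, adjusted p 0.0341 and 0.0777) were also below 0. For the NF-κB list a raised unstimulated level is argued against by its median of −0.24 between the unstimulated groups and −0.74 between the 4 h groups. For the other lists a raised unstimulated level was not tested and stays open. A shift of all genes of that expression is argued against too, as 0.01% of 10000 random lists matched for size and expression to each of these 4 lists had a median as low, the smallest share the draws can give. The interaction rests on the 2 libraries with 16.5 and 17.1% no-feature reads and raised signal inside genes, and a technical part from that stays open. Of 16 members 2 passed the interaction test alone (12 lower and 1 higher with the block), so that SIK3 may support the response is a hypothesis that assumes the file names are right, with effects of the single siRNA on other targets untested.

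Mitochondrially encoded mRNAs, of which 0 of 13 were called in the 9 comparisons by title without the replicate block and up to 10 with it, took 3.59 to 6.4 times the share of counts in replicate 2 that they took in replicate 1, in 6 of 6 groups. Multimapping reads were also higher in replicate 2 of every group, at 10.2 to 45.3% of all reads against 4.94 to 17.6% in replicate 1.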
